A study of Mus musculus with 12 samples.

How the data were processed

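The series holds 12 bulk RNA-seq libraries from tumours that grew from mCherry-labelled 4T1 cells, a mouse mammary carcinoma line of BALB/c origin, in the mammary fat pads of female BALB/c mice. Per the labels' protocols, mice were randomised 7 days after injection of the cells into 4 groups and treated intraperitoneally with Ctrl-Fc, VHH-OD-Fc, VHH-PD-1-Fc or VHH-OD-PD-1-Fc, at 5, 3.5, 2.6 and 4.3 mg/kg respectively. A VHH is the single binding domain of a camelid heavy-chain antibody (a nanobody) and Fc is the constant part of an antibody. PD-1 is an inhibitory receptor of T cells, encoded by Pdcd1. The series title names nanobodies against endogenous digoxin-like substances, and the labels do not spell out OD. Each group has 3 libraries, numbered 1 to 3 in the labels. The labels do not say that the libraries of a group come from separate animals, so p-values measure the spread between these libraries, which may be technical. The design text of the series describes another tumour and digoxin doses. It does not match the sample labels, which were used here.

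Per the labels' protocols, poly(A) RNA was enriched from total RNA and sequenced as paired reads of 150 bp. Per the submitters' processing notes, the tools included fastp 0.22.0 and HISAT2 2.2.1, and the build named is GRCh38, a human assembly, although the deposited table holds mouse gene symbols. The tool that made the FPKM values, its annotation, its use of strand and any filter are not given in the sources used here. No coordinates are printed for that reason. The authors deposited 1 table of FPKM values (fragments per kilobase of transcript and 1e+06 fragments) with 41009 gene symbols and 12 library columns, each matched to 1 sample by its name. The columns and sample titles of 1 group read OD-Fc and its treatment label reads VHH-OD-Fc, the name used here. FPKM values are not counts, so no count model was used.

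Fragments per library were estimated from the low values of 18383 genes with 1 annotated transcript, as FPKM times transcript length. The step between low values, taken as 1 fragment, gave 21.9 to 30.5 M fragments (M stands for 1e+06) per library. Between 52.3% and 67.2% of low values lay within 0.05 of a whole number of such steps, so counts were not recovered and the depth is an estimate. Gene lengths, GC content, biotypes and gene order came from GENCODE M21 (GRCm38), matched by symbol for 88.6% of the rows and 94.6% of the genes tested. The build behind the table is unknown, so that annotation served only for names, lengths, GC content and neighbours.

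Differences were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with FPKM as deposited and no further scaling. A fold change on this scale understates the change of low genes. Genes needed an FPKM of at least 1 in at least 3 of the 12 libraries, which left 14306 genes. All 12 libraries entered 1 fit with a mean per group and 1 shared estimate of the spread (8 residual degrees of freedom, 3.03 prior degrees of freedom, with a trend of variance on mean). Genes were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. The 6 contrasts were each treatment against Ctrl, VHH-OD-PD-1-Fc against each single-arm construct, and the difference from additivity, which is the effect of VHH-OD-PD-1-Fc minus the effects of both single-arm constructs, all against Ctrl and on the log2 scale. The doses in mg/kg differ, so this is not a strict factorial design. A moderated F test covered the 4 groups.

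The 44 gene lists, the tests, the rule for named genes and the settings to be varied were fixed before the data were examined. Lists with at least 5 genes among those tested (42 of 44) were tested with camera at a preset inter-gene correlation of 0.01, then with an estimated correlation and with fry. The list of Th17 and type 17 cells had 3 such genes and that of skin keratinocytes had 4, so neither was tested. Camera compares a list with the other genes, and fry asks whether the genes of a list move one way. The rule for named genes took 4 kinds of genes per comparison. The first were the 10 called genes of largest rise and the 10 of largest fall that had a mean FPKM of at least 1 in either group and libraries that did not overlap between the groups. Where fewer than 10 genes passed, the 5 highest and 5 lowest by moderated t among genes without overlap were added as values, not as calls. From each list that camera called or that held a called gene, up to 4 members of smallest p in the list's direction were taken. Pdcd1, Cd274, Cd8a, Gzmb, Ifng, Prf1, Foxp3, Atp1b1, Mki67 and some genes not printed here were always taken where measured. Pseudogenes, unnamed gene models and V segments were counted but not named under the first parts. For the difference from additivity, the rule took 5 genes per direction and no list members, without the overlap criterion, which is defined for pairs of groups. For the F test, which has no direction, the 10 smallest p were taken. Across the comparisons this rule took 750 pairs of a gene and a comparison (359 genes), more than the text can hold. The genes printed were picked from these after their values were seen, and 129 such pairs were recomputed under the alternatives. They are examples, not a random sample, and some genes that the rule took are left out of the text. Gm15850 lies outside the rule and was chosen after its values were seen, as were genes named only as neighbours or to describe single libraries.

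The steps were tested on simulated data with the real mean and the fitted spread of each of 14306 genes and 200 changed genes. The noise was normal, independent between genes and of equal spread in all groups, and changed genes were drawn from those of higher mean. For VHH-OD-Fc against Ctrl, 76% of simulated changes of 1 on the log2 scale and 96% of changes of 2 were recovered, and 4.97% of calls were false. For the difference from additivity the shares recovered were 59% and 90%, with 5.10% of calls false. The other comparisons were not simulated. In the data the median SD per gene was 0.0747 to 0.247 by group. These shares therefore hold for the simulated model and do not give the rate of false calls in the data. Alternatives covered a pseudocount of 0.1, no filter or a mean FPKM of at least 5, 3 scalings (TPM, in which all libraries have the same sum, the median of ratios and quantiles), the libraries in the fit, library weights, a replicate block, a fold of at least 2, the list tests and each library left out. The median and camera test of every list were recomputed with these alternatives where lists were tested. Added after the data were seen were the VHH-OD-PD-1-Fc libraries counted as 1 sample, removal of length and GC trends, 3 libraries that stood apart left out together, and 1 further correlation. In the first of these the lone sample is assumed to vary like the libraries of the other groups. Count-based alternatives were planned only in case the table held counts and were not run.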

Results

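RNA-seq of 4T1 tumours was compared among 4 groups of 3 libraries each: Ctrl-Fc (Ctrl below), VHH-OD-Fc, VHH-PD-1-Fc and VHH-OD-PD-1-Fc, which carries both binding arms. The estimated depth was 23.4 to 30.5 M fragments (M stands for 1e+06) in the 6 libraries without the PD-1 arm and 21.9 to 25.8 M in the 6 with it. The sum of FPKM was 327792 to 345596 without the PD-1 arm and 388142 to 401179 with it. Ribosomal protein genes held 5.16% to 6.23% of that sum without the arm and 7.77% to 9.77% with it. The first principal component held 52.8% of the variance and separated the libraries with the PD-1 arm from those without. Across genes, Pearson's r of log2 values between libraries of the different sets had a median of 0.932, and between different groups of the same set a median of 0.970. In all, 1142 genes were listed at 0 in the 6 libraries without the PD-1 arm and above 0 in the 6 with it, and 57 genes showed the reverse. The other pairings of the groups gave 1 and 0 such genes, and 0 and 2. Of the 1142 genes 60 passed the filter of the test. The labels give no batch, so a batch and the PD-1 arm cannot be told apart in any comparison across these sets.

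**Figure D1:**
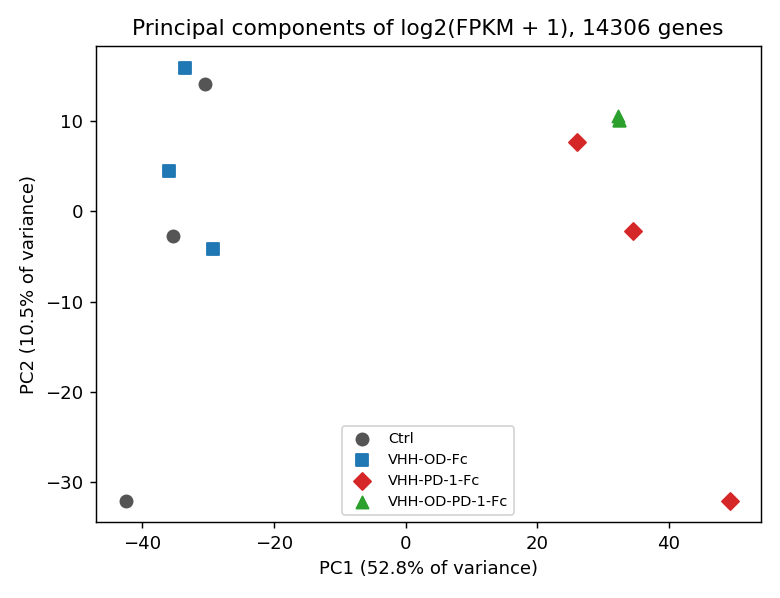
The 12 libraries on the first principal component (52.8% of variance) and the second, from log2(FPKM + 1) of 14306 genes, with 1 point per library and a marker per group. The libraries with the PD-1 arm lie to the right, and the 3 VHH-OD-PD-1-Fc libraries nearly coincide.

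The 3 VHH-OD-PD-1-Fc libraries were closer to each other than those of any other group. Their pairwise r was 0.990 to 0.991, against 0.953 to 0.984 within the other groups. Between different groups of the same set r was 0.950 to 0.991, highest for Ctrl replicate 2 with VHH-OD-Fc replicate 3, so r alone does not set these 3 libraries apart. Their median SD per gene on the log2 scale was 0.0747, against 0.140 in Ctrl, 0.123 in VHH-OD-Fc and 0.247 in VHH-PD-1-Fc. The median chi-square between pairs of them, relative to that of counting noise alone, was 3.23 to 4.50 among genes of at least 300 estimated fragments and 2.83 to 3.65 among those of 10 to 30. They were kept as 3 samples. Counts of called genes and lists, calls of named genes and correlations that involve them are also given with the 3 counted as 1 sample. Averaging them leaves the fold changes almost as they were. Camera compares a list with the other genes, so its calls and the correlations could hardly change there and do not test replication. The shared estimate of the spread uses these libraries too, so comparisons of the other groups can also depend on this choice. Single libraries stood apart in other groups. Epcam, an epithelial adhesion molecule, was at 14.3 FPKM in Ctrl replicate 1 and at 98.0 and 162 in the other Ctrl libraries. Acta1, the actin of skeletal muscle, was at 1437 FPKM in VHH-OD-Fc replicate 2. VHH-PD-1-Fc replicate 2 had 25553 genes above 0, against 30257 and 30973 in the other VHH-PD-1-Fc libraries.

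The comparison of VHH-OD-Fc with Ctrl asked what the OD arm did alone. No gene passed the test, and values are given here without a call. Cxcl9, a chemokine induced by interferon gamma, had a log2 fold change of -0.81 (SE 0.11, n = 3 per group) and Ly6i, a surface protein of the Ly6 family, of -1.26 (SE 0.16). All 32 measured genes of the type I interferon response had a negative sign (median -0.37), among them Ifi44 at -0.60 and Cmpk2 at -0.62. All 28 of the interferon gamma response did too (median -0.41). Of 15 genes of cytotoxic lymphocytes, which kill tumour cells, all were negative (median -0.64), with Gzmb (granzyme B) at -1.43 (SE 0.41) and Prf1 (perforin) at -0.85 (SE 0.27). Ctrl replicate 1 was highest in the last list, with a mean log2 value of 3.18 against 2.49 and 2.25 in the other Ctrl libraries. Without it the medians of the type I interferon and cytotoxic lists were -0.20 and -0.39, Gzmb was at -1.02 and Prf1 at -0.57. With library quality weights these medians were -0.20 and -0.34, and without Ctrl replicate 1, VHH-OD-Fc replicate 2 and VHH-PD-1-Fc replicate 2 together -0.23 and -0.41. Over all genes 0 of these passed. Adjusted over the list alone, 1, 1 and 7 genes of these 3 lists fell. Camera called all 3 lists with the preset correlation, with adjusted p = 4.8e-17, 5.9e-16 and 1.1e-12. These calls were lost with adjusted p = 0.192, 0.221 and 0.192 with an estimated correlation. Camera called the tumour epithelium list as higher with the preset correlation (median 0.17). The mean log2 value of that list was 4.06 in Ctrl replicate 1, against 4.96 and 4.73 in the other Ctrl libraries, and without Ctrl replicate 1 its median turned to -0.10.

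T cell genes had a median of -0.53 (-0.31 with library quality weights and -0.86 with a pseudocount of 0.1) and T cell inhibitory receptors of -0.33, both with adjusted p = 0.192 with an estimated correlation, and Pdcd1 was at -0.49 (SE 0.21). Adjusted over the list alone, 0 T cell genes and 1 inhibitory receptor fell, and the median of the receptors was -0.22 without VHH-OD-Fc replicate 1. Classically activated macrophages (median -0.27, 3 genes fell adjusted over the list alone) had adjusted p = 0.221 with an estimated correlation, and their median was -0.41 without Ctrl replicate 3 and -0.12 and -0.47 without VHH-OD-Fc replicates 1 and 2. The MHC class II list (-0.34) had adjusted p = 0.397 with an estimated correlation. Its median was -0.17 without Ctrl replicate 1 and -0.18 without VHH-OD-Fc replicate 3, which ended its call by camera (adjusted p = 0.21), as did library quality weights (median -0.15, adjusted p = 0.076). Without the 3 libraries left out together above it was -0.17. The lists of B cells, plasma cells and lymph node stroma and homing had medians of -0.72, -0.43 and -0.51 and were not called. Camera called all 3 as lower without Ctrl replicate 2 and without VHH-OD-Fc replicate 2, each left out alone. B cell genes had mean log2 values of 2.85, 0.99 and 3.13 in Ctrl replicates 1 to 3 and of 1.56, 2.84 and 0.97 in the VHH-OD-Fc libraries, so this list differed between single libraries of both groups, and how far this bears on the T cell and cytotoxic lists was not tested. Lists of neighbouring tissue had positive medians, with 0 genes past the test. Adipocyte genes had a median of 1.08 (0.60 without a filter and 0.46 with library quality weights), with Adipoq (adiponectin) at 1.54 (SE 0.57), and skeletal muscle genes of 1.73. Their adjusted p was 0.192 and 0.397 with an estimated correlation. Both lists peaked in VHH-OD-Fc replicate 2, where the mean log2 value of the muscle list was 6.18, against 1.17 and 3.95 in the other VHH-OD-Fc libraries. Without that library the adipocyte median was 0.56 and the muscle median 0.44, which ended the call of the latter (adjusted p = 0.052). The muscle median was 1.08 and 2.62 without Ctrl replicates 1 and 2 and 2.99 without VHH-OD-Fc replicate 1. With the same 3 libraries left out together it turned to -0.0648 and was not called (adjusted p = 0.69), while the adipocyte median was 0.44. Fibroblast and extracellular matrix genes had a median of 0.30, with 25 of 25 positive and adjusted p = 0.249 with an estimated correlation, and 0.15 without Ctrl replicate 1 and 0.11 without the 3 libraries.

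Limma called 0 of 14306 genes for VHH-OD-Fc against Ctrl. The smallest adjusted p was 0.108, and 449 genes (3.14%) had an unadjusted p under 0.05. Groups did not overlap for 10.2% of genes, where chance gives 10%. Library quality weights in the same tool gave 4 genes, and leaving out VHH-OD-Fc replicate 3 gave 1. Camera called 17 of 42 lists, 7 higher and 10 lower, against 0 with an estimated correlation and 0 with fry. It called 28 without Ctrl replicate 2 and 27 without VHH-OD-Fc replicate 2.

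**Figure D2:**
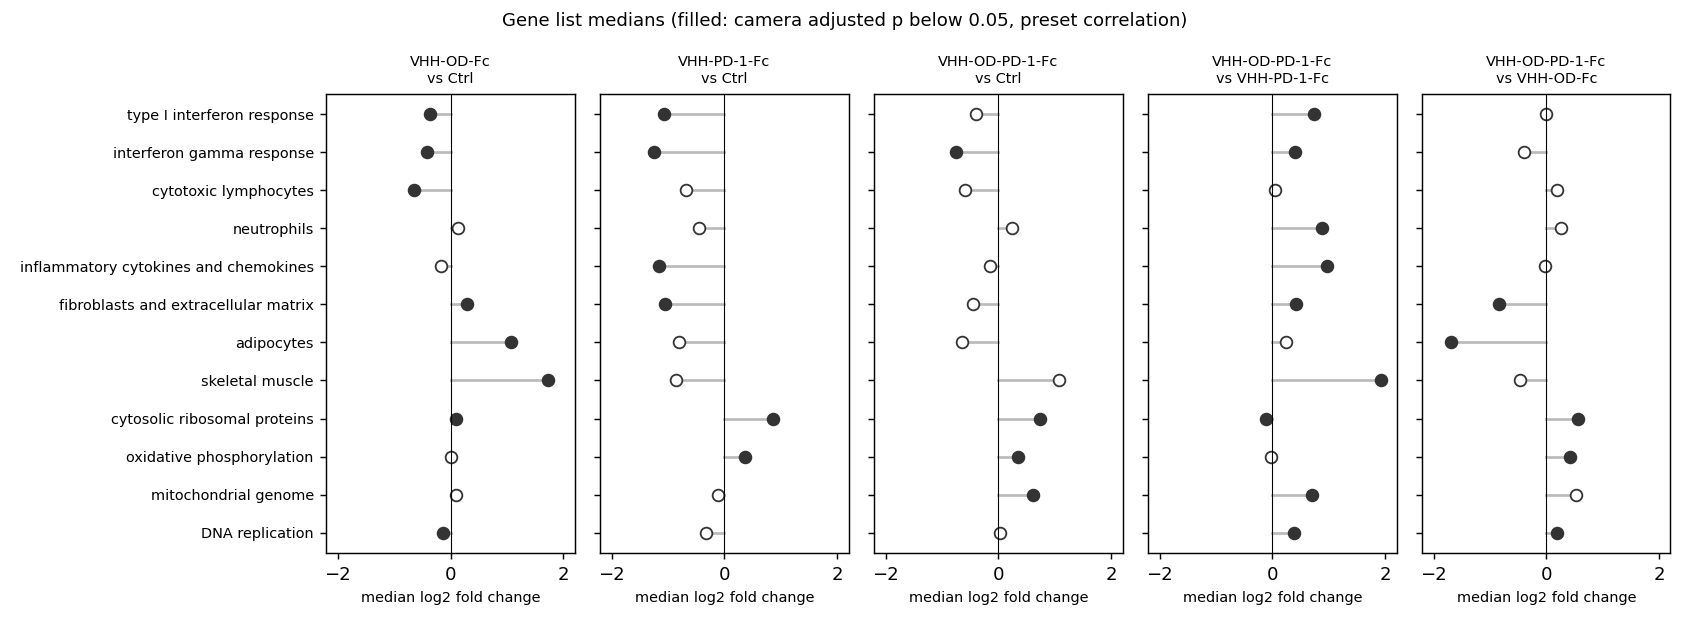
Median log2 fold change of 12 gene lists in 5 comparisons, with 1 circle per list and filled circles where camera's adjusted p was under 0.05 with the preset correlation. No list kept its call with an estimated correlation. Signs turn under another scaling for the type I interferon and inflammatory lists in VHH-OD-PD-1-Fc against VHH-OD-Fc, for DNA replication in VHH-OD-PD-1-Fc against Ctrl and VHH-OD-Fc, for cytotoxic lymphocytes in VHH-OD-PD-1-Fc against VHH-PD-1-Fc and for the mitochondrial genome in VHH-PD-1-Fc against Ctrl. Scaling moves the median of all genes as well.

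VHH-PD-1-Fc against Ctrl asked what the PD-1 arm did alone. Cytosolic ribosomal protein genes rose, 34 of 36 over all genes and 35 adjusted over the list alone (median 0.86), with Rps20 at 1.44 (SE 0.11, n = 3 per group) and Rps27 at 1.32 (SE 0.11). Of 27 genes of oxidative phosphorylation, 15 rose and 1 fell (17 and 1 adjusted over the list alone; median 0.37), and Cox7a2, a subunit of cytochrome c oxidase, rose by 1.19 (SE 0.11). Both lists had adjusted p = 0.470 with an estimated correlation. The oxidative phosphorylation median was 0.11 after removal of length and GC trends and 0.14 after rescaling to TPM, and the ribosomal median 0.33 by quantiles. Type I interferon genes fell, 28 of 32 by either adjustment, over all genes or adjusted over the list alone (median -1.07), among them Cmpk2 (-1.98, SE 0.18) and Ifi44 (-1.48, SE 0.12). Of 28 interferon gamma genes 25 fell, and also 25 adjusted over the list alone (median -1.25), with the guanylate-binding proteins Gbp10 at -2.13 (SE 0.14) and Gbp5 at -2.14 (SE 0.20). Both interferon lists had adjusted p = 0.826 with an estimated correlation.

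Extracellular matrix and fibroblast genes fell in VHH-PD-1-Fc, 17 of 25 over all genes and 19 adjusted over the list alone (median -1.05), including the collagen Col5a1 (-1.46, SE 0.16). In the G2 and M phase list 15 of 25 fell, and 18 adjusted over the list alone (median -0.54), with the mitotic kinesin Kif20a at -1.62 (SE 0.14) and the proliferation marker Mki67 at -1.29 (SE 0.24). Immediate early and heat shock genes fell in 13 of 21 cases and rose in 1, with equal counts adjusted over the list alone (median -0.97), and the AP-1 subunit Jun was at -2.09 (SE 0.14). Inflammatory cytokines fell in 11 of 24 cases by both adjustments, over all genes and adjusted over the list alone (median -1.17). Classically activated macrophage genes fell in 9 of 16 cases, and 10 adjusted over the list alone (median -0.77), with Cxcl10 at -1.94 and Tnf at -1.13. Each of these 5 lists had adjusted p = 0.826 with an estimated correlation. Their calls by camera with the preset correlation also depended on single libraries. The matrix list lost its call without VHH-PD-1-Fc replicate 1 (adjusted p = 0.051). The G2 and M phase list lost it without Ctrl replicates 1 and 3 (0.062 and 0.055) and VHH-PD-1-Fc replicates 1 and 2 (0.20 and 0.077), in each case with 1 library left out at a time. Immediate early genes lost it without Ctrl replicate 2 (0.11) and VHH-PD-1-Fc replicates 1 (0.051) and 2 (0.10, median -0.61). Inflammatory cytokines lost it without Ctrl replicates 1 and 2 (0.051 and 0.085) and VHH-PD-1-Fc replicate 2 (0.15, median -0.64), and classically activated macrophages without Ctrl replicate 2 (0.061) and VHH-PD-1-Fc replicate 2 (0.077). Rescaling to TPM ended the calls of the last 3 lists (0.10, 0.19 and 0.10, with the macrophage median at -1.17), library quality weights those of inflammatory cytokines and macrophages (0.16, median -0.77, and 0.055) and a mean FPKM of at least 5 that of immediate early genes (0.052). Without the 3 libraries apart inflammatory cytokines (0.099, median -0.54) and the G2 and M phase (0.16) were not called. Cd274, which encodes the ligand of PD-1, fell by 2.03 (SE 0.33, adjusted p = 0.00081), and Gzmb by 1.51 (SE 0.41, adjusted p = 0.011). The groups overlapped for Gzmb. It was at 26.9, 16.2 and 7.15 FPKM in Ctrl replicates 1 to 3 and at 3.08, 3.74 and 7.75 FPKM in VHH-PD-1-Fc replicates 1 to 3. Pdcd1 was at -0.14 (SE 0.21, adjusted p = 0.62) and Cd8a, a marker of cytotoxic T cells, at -0.57 (SE 0.31, adjusted p = 0.16), neither past the test. Cxcl13, a chemokine for B cells, fell by 3.31 (SE 0.65), while Gpx1, a glutathione peroxidase, rose by 1.78 (SE 0.16). Cxcl13 is in the list of lymph node stroma and homing, which camera did not call. The mean log2 value of that list varied between Ctrl libraries, at 3.38, 2.38 and 3.15 in replicates 1 to 3. In VHH-PD-1-Fc replicates 1 to 3 it was 1.34, 1.20 and 1.52.

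For VHH-PD-1-Fc against Ctrl limma called 6707 genes, 2092 higher and 4615 lower. The shared estimate of the spread also uses the VHH-OD-PD-1-Fc libraries, so this count depends on taking them as separate samples. With these libraries counted as a single sample fewer genes were called in both directions. The median of all genes was -0.19, so list medians are to be read against it, and it was -0.43 after rescaling to TPM, -0.04 by the median of ratios and -0.02 by quantiles. The split of higher and lower genes moved with it, to 1346 and 6800, 2954 and 3113, and 2815 and 2593. Camera called 9 lists, 2 higher and 7 lower (5 in all without VHH-PD-1-Fc replicate 2), against 0 with an estimated correlation and 25 with fry. Fold changes fell with transcript length across genes, which are not independent replicates (Spearman's rho -0.32), with a median of 0.22 among genes under 1265 bases and -0.38 among those over 4806. In VHH-OD-Fc against Ctrl that rho was 0.00. For VHH-OD-PD-1-Fc it was -0.35 against Ctrl, -0.36 against VHH-OD-Fc and -0.01 against VHH-PD-1-Fc.

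**Figure D3:**
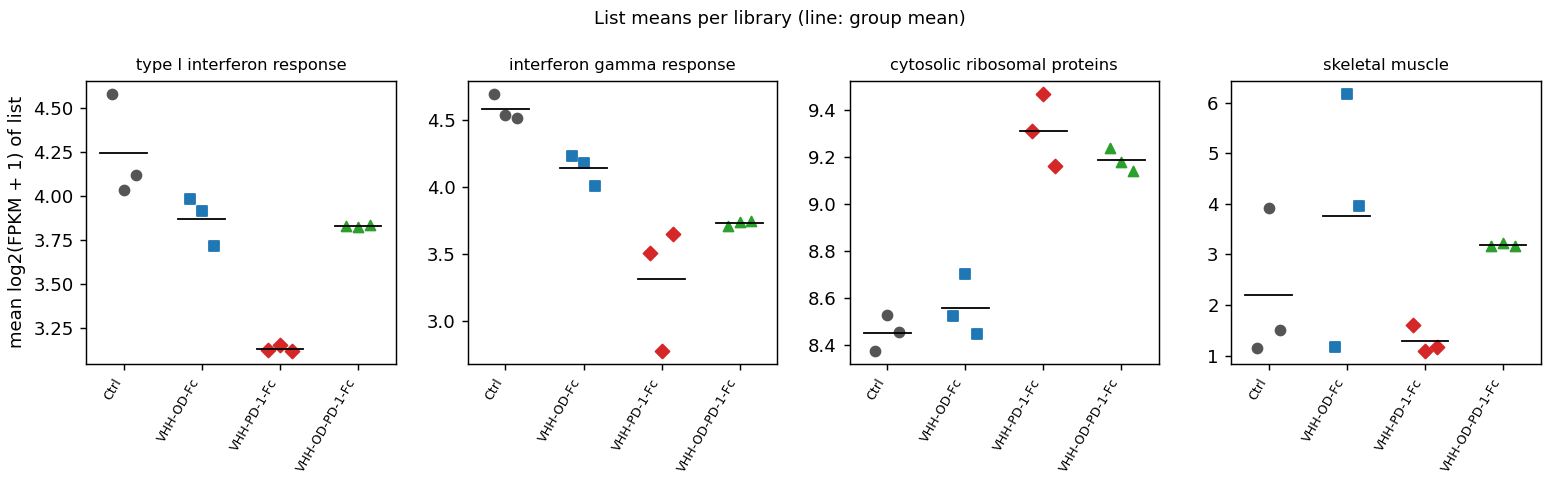
Mean log2(FPKM + 1) of 4 gene lists in each library, with 1 point per library and a line at each group's mean. Ribosomal protein genes are higher in the 6 libraries with the PD-1 arm, and the muscle list is at 3.16 to 3.22 in the 3 VHH-OD-PD-1-Fc libraries and at 1.14 to 3.93 in Ctrl.

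VHH-OD-PD-1-Fc against Ctrl asked what both arms did together. Cldn6, a tight junction protein, rose by 4.39 (SE 0.36, n = 3 per group). Ribosomal protein genes rose, 33 of 36 over all genes and 34 adjusted over the list alone (median 0.74), with Rps20 at 1.48 (SE 0.11). Oxidative phosphorylation genes rose in 14 of 27 cases and fell in 1, and 15 and 2 adjusted over the list alone (median 0.35). Both lists had adjusted p = 0.725 with an estimated correlation. Interferon gamma genes fell in 19 of 28 cases and rose in 1, and 20 and 1 adjusted over the list alone (median -0.75), with Gbp10 at -2.13 (SE 0.14). Genes of the mitochondrial genome rose in 6 of 13 cases, and 7 adjusted over the list alone (median 0.60). The last 2 lists had adjusted p = 0.999 with an estimated correlation. After removal of length and GC trends the oxidative phosphorylation median was 0.0689 and the mitochondrial genome lost its call (median 0.41, adjusted p = 0.11). After rescaling to TPM these medians were 0.12 and 0.37. By quantiles the ribosomal median was 0.29 and the mitochondrial genome was at 0.15 and not called (adjusted p = 0.35). The type I interferon list (median -0.39) was not called. It was called without Ctrl replicate 2 (adjusted p = 0.019) and without Ctrl replicate 3 (adjusted p = 0.047), and with quantile normalization (adjusted p = 0.019).

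Cd274 fell by 1.44 (SE 0.33, adjusted p = 0.0057) in VHH-OD-PD-1-Fc against Ctrl, and Trac, a constant region of the T cell receptor, by 1.16 (SE 0.21). Pdcd1 was at -0.56 (SE 0.21, adjusted p = 0.049), and its call was lost when any 1 Ctrl library, any 1 VHH-OD-PD-1-Fc library, VHH-OD-Fc replicate 2 or 3, or VHH-PD-1-Fc replicate 3 was left out. Retnlg, a neutrophil gene, rose by 2.18 (SE 0.46). Limma called 6036 genes, 2158 higher and 3878 lower. The median of all genes was -0.14, and it was -0.37, -0.03 and -0.02 after rescaling to TPM, by the median of ratios and by quantiles. The split became 1415 and 6192, 2854 and 2782, and 2670 and 2573. With the VHH-OD-PD-1-Fc libraries counted as 1 sample 1329 genes were called, 1327 of them also called before. Among the genes named here that ended the calls of Cd274, Pdcd1, Trac and Retnlg and kept those of Cldn6, Rps20 and Gbp10. Of the ribosomal protein genes 20 then rose, of the oxidative phosphorylation genes 7, of the mitochondrial genome 0, and 6 interferon gamma genes fell. Camera called 4 lists, 3 higher and 1 lower, the same 4 with the libraries counted as 1 sample, against 0 with an estimated correlation and 17 with fry. It called 7 without Ctrl replicate 1 and 8 without Ctrl replicate 2.

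VHH-OD-PD-1-Fc against VHH-PD-1-Fc asked what the OD arm added to the PD-1 arm, within the set of libraries that carry it. Kif21b, a kinesin motor, rose by 2.46 (SE 0.10, n = 3 per group, adjusted p = 3.7e-07), and Atmin, a zinc finger transcription factor, by 1.56 (SE 0.07, adjusted p = 6.5e-07). Cldn6 rose by 3.33 (SE 0.36, adjusted p = 0.0023) and Jun by 1.46 (SE 0.14, adjusted p = 0.0014), while Itgb5, an integrin subunit, fell by 0.99 (SE 0.10, adjusted p = 0.0014). Gm15850, an unnamed gene model, was at 23.5 FPKM in VHH-OD-PD-1-Fc and at 0.0391, 0.0567 and 0.00890 in Ctrl, VHH-OD-Fc and VHH-PD-1-Fc. It lies next to Kif21b on chromosome 1 on the opposite strand, and whether counting used the strand is not given in the sources used here. Kif21b itself was at 8.36 FPKM in VHH-OD-PD-1-Fc and at 2.16, 1.75 and 0.700 in the other groups. Mroh3 and Inava, the next genes on its other side, were at 0.295 and 14.1 FPKM in VHH-OD-PD-1-Fc and at 0.437 and 18.0 in VHH-PD-1-Fc. Atmin was at 20.98 FPKM, against 5.86 to 6.46 in the other groups.

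Type I interferon genes rose in VHH-OD-PD-1-Fc over VHH-PD-1-Fc in 6 of 32 cases, and 24 adjusted over the list alone (median 0.73), with Oas1a, an antiviral enzyme, at 0.83 (SE 0.11, adjusted p = 0.015) and Cmpk2 at 1.27 (SE 0.18, adjusted p = 0.019). For DNA replication genes 0 of 25 passed, and 11 rose adjusted over the list alone (median 0.38). In the immediate early and heat shock list 1 of 21 rose, and 12 adjusted over the list alone (median 0.63). For the mitochondrial genome 0 of 13 passed, and 11 rose adjusted over the list alone (median 0.70). These 4 lists had adjusted p = 0.586 with an estimated correlation. The immediate early median was 0.41 without VHH-PD-1-Fc replicate 2. Inflammatory cytokines (median 0.97, and 0.47 without the same library; 0 of 24 passed, 11 adjusted over the list alone) had adjusted p = 0.675 with an estimated correlation. Neutrophil genes (median 0.87; 0 of 27 passed, 4 adjusted over the list alone) and interferon gamma genes (median 0.41; 0 of 28 passed, 2 adjusted over the list alone) had adjusted p = 0.705 with an estimated correlation. Without VHH-PD-1-Fc replicate 2 the interferon gamma median was 0.06 and its call was lost (adjusted p = 0.22). Leaving out the 3 libraries apart gave the same 3 medians. Skeletal muscle genes had a median of 1.92 in this comparison (0.97 without a filter), with 18 of 18 positive, 0 past the test and adjusted p = 0.763 with an estimated correlation, and lost their call by camera without VHH-PD-1-Fc replicate 3 (adjusted p = 0.054). Amphiregulin (Areg), a growth factor, rose by 2.75 (SE 0.39), and Spry1, an inhibitor of growth factor signals, fell by 1.70 (SE 0.28). Cd274 (0.59, SE 0.33), Cd8a (-0.15, SE 0.31) and Gzmb (0.64, SE 0.41) did not pass.

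Limma called 120 genes for VHH-OD-PD-1-Fc against VHH-PD-1-Fc, 77 higher and 43 lower, and the split was 57 and 52 by the median of ratios and 38 and 48 by quantiles. With the VHH-OD-PD-1-Fc libraries counted as 1 sample 3 genes were called, Gm15850, Kif21b (adjusted p = 0.0011) and Atmin (adjusted p = 0.0019). Leaving out a VHH-OD-PD-1-Fc library (replicates 1, 2 and 3) gave 10, 12 and 9 genes, a VHH-PD-1-Fc library 460, 227 and 538, a Ctrl library 193, 55 and 44, and a VHH-OD-Fc library 44, 44 and 43. Of the 14 called genes that were recomputed, 9 lost their call when at least 1 library was left out. Among those named here these were Areg, Oas1a, Cmpk2 and Spry1, each lost without any 1 VHH-OD-PD-1-Fc library, and Kif21b, Atmin, Cldn6, Jun and Itgb5 kept theirs. If the 3 VHH-OD-PD-1-Fc libraries are repeats of 1 RNA or pool, leaving out 1 of them cannot test the calls that were kept. Such changes may then belong to that tumour or pool and not to the construct. Camera called 17 lists, 15 higher and 2 lower (the same 17 with the VHH-OD-PD-1-Fc libraries counted as 1 sample and 11 in all without VHH-PD-1-Fc replicate 2), against 0 with an estimated correlation and 1 with fry.

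**Figure D4:**
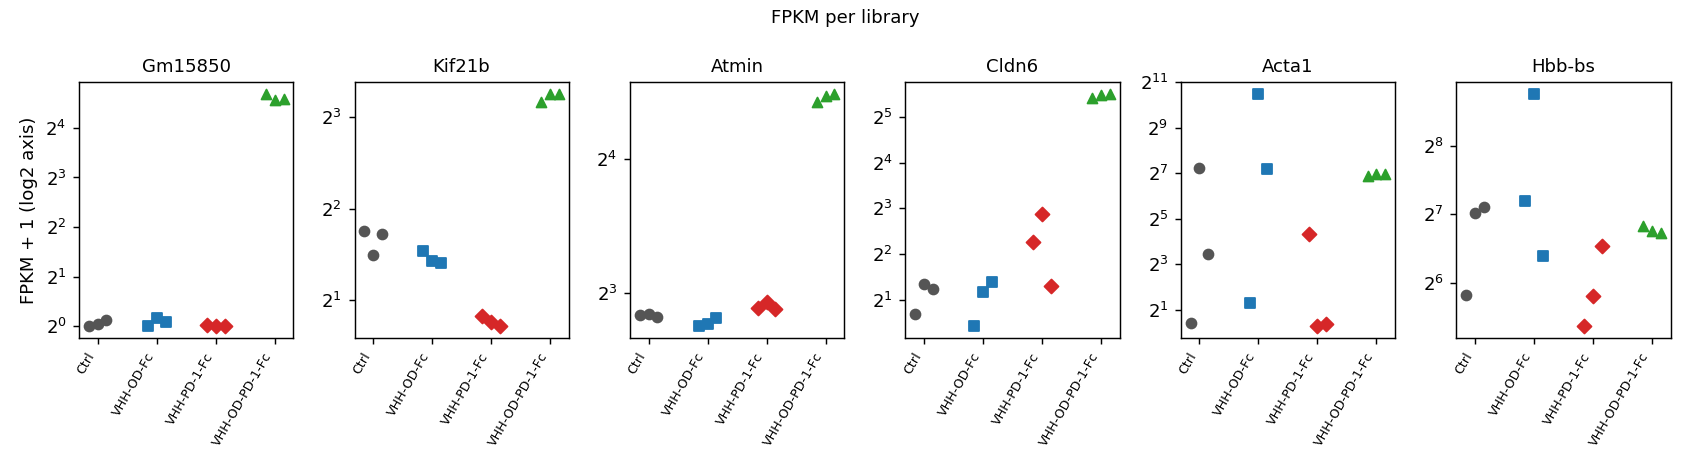
FPKM + 1 of 6 genes on a log2 axis, with 1 point per library. Gm15850, Kif21b, Atmin and Cldn6 are highest in the 3 VHH-OD-PD-1-Fc libraries, where Acta1 and Hbb-bs also lie close together, while these vary between libraries of other groups.

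VHH-OD-PD-1-Fc against VHH-OD-Fc asked what the PD-1 arm added to the OD arm. Ribosomal protein genes rose, 31 of 36 over all genes and 33 adjusted over the list alone (median 0.56), and of 27 oxidative phosphorylation genes 15 rose and 2 fell, and 17 and 3 adjusted over the list alone (median 0.42). Both lists had adjusted p = 0.937 with an estimated correlation. Fibroblast and extracellular matrix genes fell in 15 of 25 cases, and 16 adjusted over the list alone (median -0.84), with the growth factor receptor Pdgfra at -0.99 (SE 0.13, n = 3 per group). Myofibroblast and pericyte genes fell in 6 of 12 cases, and 8 adjusted over the list alone (median -0.78), with Rgs5, a pericyte marker, at -1.56 (SE 0.22). Endothelial genes fell in 10 of 18 cases by both adjustments, over all genes and adjusted over the list alone (median -0.53), with Pecam1 at -0.90 (SE 0.13). Adipocyte genes fell in 10 of 12 cases, also by both, over all genes and adjusted over the list alone (median -1.68), with Cidec, a lipid droplet protein, at -2.38 (SE 0.59). DNA replication genes rose in 6 of 25 cases, and 2 adjusted over the list alone (median 0.19). That median turned to -0.03 after rescaling to TPM, when the median of all genes also moved, from -0.11 to -0.34. These 5 lists had adjusted p = 0.959 with an estimated correlation. Without VHH-OD-Fc replicate 2 camera no longer called the adipocyte and DNA replication lists (adjusted p = 0.063 and 0.12). After removal of length and GC trends the ribosomal and oxidative phosphorylation medians were 0.36 and 0.13, after rescaling to TPM 0.33 and 0.19, and by quantiles the former was 0.17. Rescaling to TPM gave -1.20 for myofibroblasts and -0.80 for endothelium and ended the calls of adipocytes and DNA replication (adjusted p = 0.14 and 0.24). Adipocytes were also not called with library quality weights (0.077) or with only the groups contrasted (0.054), and DNA replication not without a filter (0.15). Neither was called without the 3 libraries apart (0.16 and 0.097), and the median of the latter was 0.28 by the median of ratios. With a mean FPKM of at least 5 DNA replication, myofibroblasts and endothelium were not called (0.11, 0.089 and 0.059). Mmp2, a matrix metalloproteinase, fell by 2.73 (SE 0.26) and Mki67 by 0.99 (SE 0.24).

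For VHH-OD-PD-1-Fc against VHH-OD-Fc limma called 5712 genes, 2209 higher and 3503 lower. The median of all genes was -0.11, and -0.34, -0.02 and -0.01 after rescaling to TPM, by the median of ratios and by quantiles, with splits of 1369 and 5616, 2752 and 2725, and 2609 and 2467. With the VHH-OD-PD-1-Fc libraries counted as 1 sample 1098 genes were called, 1095 of them also called before. Among the genes named here Cidec and Mki67 then lost their calls, and Pdgfra, Rgs5, Pecam1 and Mmp2 kept theirs. Of the ribosomal protein genes 10 then rose and of the oxidative phosphorylation genes 6, and 3 matrix, 2 myofibroblast, 2 endothelial and 0 adipocyte genes fell. Camera called 7 lists, 3 higher and 4 lower, and 6 with the libraries counted as 1 sample, when DNA replication lost its call (adjusted p = 0.057), against 0 with an estimated correlation and 10 with fry.

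The difference from additivity asked whether both arms together differed from the sum of the single arms. Kif21b was above that sum by 2.66 (SE 0.14, n = 3 per group, adjusted p = 6.8e-06) and Atmin by 1.61 (SE 0.10, adjusted p = 1.9e-05). Cldn6 was above it by 3.43 (SE 0.50, adjusted p = 0.030), Cmpk2 by 1.89 (SE 0.26, adjusted p = 0.022) and Apol11b by 1.63 (SE 0.20, adjusted p = 0.013). Itgb5 was below it, at -1.10 (SE 0.14, adjusted p = 0.013). Of 32 type I interferon genes 4 were above the sum, and 28 adjusted over the list alone (median 1.07), with adjusted p = 0.239 with an estimated correlation. Limma called 16 genes, 13 higher and 3 lower. With the VHH-OD-PD-1-Fc libraries counted as 1 sample 3 were called, among them Kif21b (adjusted p = 0.0031) and Atmin (adjusted p = 0.0081). Leaving out a Ctrl library (replicates 1 and 3) gave 8 and 4 genes, a VHH-OD-Fc library (replicates 1 to 3) 7, 9 and 7, a VHH-PD-1-Fc library 72, 77 and 105 and any VHH-OD-PD-1-Fc library 3. Of the 6 genes named here 4 lost their call when at least 1 library was left out, and Kif21b and Atmin did not. If the 3 VHH-OD-PD-1-Fc libraries are repeats of 1 RNA or pool, leaving out 1 of them cannot test these calls. Counting them as 1 sample takes the spread from the other groups and cannot test them either. The differences may then belong to that tumour or pool and not to the construct. Camera called 16 lists, 13 higher and 3 lower, the same 16 with the libraries counted as 1 sample, against 0 with an estimated correlation and 3 with fry.

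The moderated F test over the 4 groups called 7110 of 14306 genes in limma, and 4227 with the VHH-OD-PD-1-Fc libraries counted as 1 sample. Across genes, which are not independent replicates, fold changes against Ctrl of VHH-PD-1-Fc and VHH-OD-PD-1-Fc had r = 0.863, and 0.862 with the VHH-OD-PD-1-Fc libraries counted as 1 sample. Unchanged groups that share the controls gave r = 0.503 in simulation, and the covariance was 0.317 against 0.0248. Both treatments had 1593 genes higher and 3234 lower, where independent calls would give 316 and 1251, and 10 genes were called in opposite directions. With the VHH-OD-PD-1-Fc libraries counted as 1 sample there were 543 and 735, where independent calls would give 69.9 and 201, and 2 in opposite directions. The values for independent calls leave out the shared Ctrl libraries, to which part of the excess may belong. VHH-OD-Fc and VHH-PD-1-Fc had r = 0.241 and VHH-OD-Fc and VHH-OD-PD-1-Fc r = 0.286 (0.283 as 1 sample), each below the simulated 0.4995 and 0.502. Their covariances were 0.0326 and 0.0381, against 0.0245 and 0.0247. The simulations gave every group the same spread per gene and no change. In the data the spread differed between groups and many genes differed across the 2 sets of libraries. The simulated values are therefore no exact reference, and an r below them has no clear meaning. The fold changes of the OD arm without and with the PD-1 arm, which share no library, had r = 0.0781 (0.0752 as 1 sample, Spearman's rho -0.0982), and r turned to -0.0446 without VHH-OD-Fc replicate 2. Without Ctrl replicate 2 the r of VHH-OD-Fc with VHH-PD-1-Fc was 0.389 and with VHH-OD-PD-1-Fc 0.437, and without VHH-OD-Fc replicate 1 the former was 0.149 and the r of the OD arm without and with the PD-1 arm 0.178.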

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

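Chosen after the results were seen were the tests of depth and of a batch for the split of the libraries, both tests on the VHH-OD-PD-1-Fc libraries, the count of libraries with the PD-1 arm on each side of the regroupings, the judgement that these say nothing on chance for the difference from additivity, the regroupings of 10 samples for the F test, and, for the interferon genes, the demand that a value pass its bound by more than 1 standard error, which left open 2 explanations that the bounds alone would have excluded.

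The effect of both arms together differed from the sum of the single arms for 16 genes by the test of that difference. Among the genes named here the difference was 3.43 for Cldn6, 2.66 for Kif21b, 1.89 for Cmpk2, 1.63 for Apol11b, 1.61 for Atmin and -1.10 for Itgb5 on the log2 scale. Of these 6 genes 4 (Cldn6, Cmpk2, Apol11b and Itgb5) lost their call when at least 1 library was left out. Leaving out a VHH-OD-PD-1-Fc library cannot test the calls that were kept if these libraries are repeats of 1 RNA or pool. With 1 library left out the test called 3 to 105 genes. Camera called the same difference, with the preset correlation and not with an estimated one, for 16 lists. Their medians were 1.07 for type I interferon, 0.73 for interferon gamma, 1.10 for classically activated macrophages, 1.12 for inflammatory cytokines, 0.69 for neutrophils, 0.68 for cytotoxic lymphocytes, 0.47 for T cell inhibitory receptors and 0.36 for MHC class I. They were 0.43 for the G2 and M phase, 0.53 for DNA replication, 0.64 for the mitochondrial genome, 0.51 for the unfolded protein response and 0.52 for immediate early genes. They were negative for adipocytes (-0.81), myofibroblasts and pericytes (-0.32) and ribosomal proteins (-0.25). Several medians moved by over 1.5 times, or lost their call by camera, without 1 library. Cytotoxic lymphocytes were at 0.37 without Ctrl replicate 1 and 0.39 without VHH-PD-1-Fc replicate 2. Without the latter MHC class I was at 0.20, inflammatory cytokines at 0.74, the mitochondrial genome at 0.40, the unfolded protein response at 0.30 and ribosomal proteins at -0.15. Neutrophils lost their call without VHH-OD-Fc replicate 1 (median 0.42) and VHH-PD-1-Fc replicates 2 and 3 (0.55 and 0.60), with 1 library left out at a time, and were at 1.11 without VHH-OD-Fc replicate 2 and 1.07 without VHH-PD-1-Fc replicate 1. T cell inhibitory receptors lost theirs without Ctrl replicate 2 (0.44), VHH-OD-Fc replicate 3 (0.41), VHH-PD-1-Fc replicates 2 and 3 (0.33 and 0.44) and VHH-OD-PD-1-Fc replicate 1 (0.40). Adipocytes were at -0.47 without Ctrl replicate 1, -1.23 and -0.35 without VHH-OD-Fc replicates 1 and 2 and -0.49 without VHH-PD-1-Fc replicate 3. Myofibroblasts and pericytes were at -0.19 without Ctrl replicate 1 and -0.16 without VHH-PD-1-Fc replicate 3, when immediate early genes were at 0.82. Calls also ended with library quality weights for cytotoxic lymphocytes (0.28), T cell inhibitory receptors (0.34) and adipocytes (-0.0506), and for these receptors after removal of length and GC trends and with a pseudocount of 0.1. They ended for cytotoxic lymphocytes with a mean FPKM of at least 5 (0.54), and without the 3 libraries apart for MHC class I (0.15), adipocytes (-0.11) and ribosomal proteins (-0.0386). Without these 3 libraries the medians were 0.22 for cytotoxic lymphocytes, 0.46 for interferon gamma, 0.68 for inflammatory cytokines, 0.33 for DNA replication, 0.28 for the unfolded protein response and -0.19 for myofibroblasts and pericytes. Inflammatory cytokines were at 0.64 and myofibroblasts and pericytes at -0.19 with library quality weights, immediate early genes at 0.84 with a pseudocount of 0.1 and adipocytes at -0.29 without a filter.

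Among 100 regroupings of the 12 libraries 4 gave at least 16 genes for this difference, the real one included, and 30 gave at least 16 lists (highest other 23). Most regroupings mix libraries with and without the PD-1 arm within their groups, which widens the spread there, so neither count says whether chance is excluded. The 3 other regroupings of that many genes gave 112, 1079 and 1596 genes, which points to a structure of the samples. In each of them 5 of the 6 libraries with the PD-1 arm lay on 1 side of the difference. Of the regroupings drawn 11 were of that kind, and 3 of these gave at least 16 genes. Of the 39 and 49 with 3 and 4 such libraries on the larger side 0 did.

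Many genes differed between the libraries with and without the PD-1 arm. After the trends on length and GC content were removed 5450 genes were still called for VHH-PD-1-Fc against Ctrl, which argues against these trends as the whole cause. The mean estimated depth with the arm was 0.936 of that without it and the ranges overlapped, which argues against depth. A library or sequencing batch may have contributed: 1142 genes, of which 667 have symbols of the form Gm plus a number, were listed at 0 in the 6 libraries without the PD-1 arm and above 0 in the 6 with it. The median of their mean FPKM with the arm was 0.135, and 60 passed the filter of the test, so few of the called genes are among them. Since every library with the arm lies on 1 side, a batch and an effect of the PD-1 arm cannot be told apart here.

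The 3 VHH-OD-PD-1-Fc libraries differed little from each other. The median chi-square relative to counting noise grew by a factor of 1.20 from genes of few to genes of many fragments, against 4.31, 4.69 and 9.86 in Ctrl, VHH-OD-Fc and VHH-PD-1-Fc, which is consistent with repeat libraries of 1 RNA or 1 pool. The bound of 2 set for separate samples was not met by every pair of the other groups, since 1 Ctrl pair had 1.88. Carry-over of muscle would differ between separately excised tumours, but the SD of the muscle list was 0.0304, against 1.51, 2.51 and 0.27 in the other groups. The last group shows that a low SD occurs where little muscle is present. The list's mean log2 value was 1.09 to 1.60 there and 3.16 to 3.22 in the VHH-OD-PD-1-Fc libraries, which argues against a lack of muscle as the reason for their low SD. How these libraries were made is not given in the sources used here.

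All measured genes of the type I and gamma interferon lists had a negative sign in VHH-OD-Fc against Ctrl, but 0 of 14306 genes passed the test, both lists lost their call with an estimated correlation (adjusted p = 0.192 and 0.221), fry called 0 lists and 5 of 10 splits gave at least as many lists. Whether there was a change therefore stays open, and no technical explanation for one was excluded. Each SE given next is that of the groups' difference in the list's mean log2 value per library, not of the median. Without VHH-OD-Fc replicate 2, which held muscle and fat transcripts, the type I interferon median was -0.41 (SE 0.24), so such carry-over is unlikely to be needed, but its error reaches the bound. A control library with a high interferon level may account for part of it, since without Ctrl replicate 1 the median was -0.20 (SE 0.11). Fewer leukocytes of all kinds stay open too, with medians of 0.13 (SE 0.45) for neutrophils, -0.18 (SE 0.27) for macrophages and -0.11 (SE 0.24) for monocytes. An effect of the OD arm also stays open and was not tested apart from these.

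Splits of 3 against 3 libraries number 10, too few for a share under 0.05. Where only 1 of the 2 groups has the PD-1 arm, every other split mixes libraries with and without it. That widens the spread within groups, so the low gene counts of those splits would also follow from a batch. For VHH-OD-Fc against Ctrl 10 of 10 gave at least the 0 genes of the real split (highest other 25) and 5 at least its 17 lists (highest other 25). For VHH-PD-1-Fc against Ctrl the real split had 6707 genes and the highest other 7, so that 1 gave as many, and 9 gave at least its 9 lists (highest other 21). For VHH-OD-PD-1-Fc against Ctrl 1 gave 6036 genes (highest other 0) and 10 gave at least 4 lists (highest other 15). Against VHH-PD-1-Fc 1 gave 120 genes (highest other 1) and 1 gave 17 lists (highest other 12). Against VHH-OD-Fc 1 gave 5712 genes (highest other 0) and 7 gave at least 7 lists (highest other 16). For the F test 1 of 100 regroupings of the 12 libraries gave 7110 genes (highest other 17). With the VHH-OD-PD-1-Fc libraries counted as 1 sample 2 of 100 gave at least 4227 (highest other 4252). Under no difference among the groups at all every regrouping of separate samples is as likely, so chance is excluded for that case only under the following conditions. The first count needs the 12 libraries to be separate samples. The second needs the libraries of the other groups to be separate samples and a mean of 3 libraries to vary like a single library. The labels do not say whether the libraries of a group come from separate animals. Neither count says which groups differ, or whether a batch that coincides with the PD-1 arm parts them. Apart from the names of the groups, the regrouping that gave 4252 differed from the real one only in how the Ctrl and VHH-OD-Fc libraries were parted into 2 groups.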

How the results depend on the processing

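Chosen after the data were seen were the VHH-OD-PD-1-Fc libraries counted as 1 sample, the removal of length and GC trends, the 3 libraries apart left out together, and the correlation of the OD arm without and with the PD-1 arm. Over the alternatives 3044 values of the genes recomputed gave 2820 that kept their direction and side of the threshold, 139 no longer past it, 58 newly past it, 27 uncalled values of changed sign and 0 called values that reversed. Where values below moved, the cause was not tested unless stated. Comparisons are named by their groups, and counts are of genes unless lists are named.

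A pseudocount of 0.1 gave 10 for the difference from additivity. No filter gave 2 for VHH-OD-Fc against Ctrl and 188 for VHH-OD-PD-1-Fc against VHH-PD-1-Fc, with 28, 29 and 24 lists for VHH-OD-Fc, VHH-PD-1-Fc and VHH-OD-PD-1-Fc against Ctrl and 13 lists for VHH-OD-PD-1-Fc against VHH-OD-Fc. A mean FPKM of at least 5 tests fewer genes and gave 3741 and 3293 for VHH-PD-1-Fc and VHH-OD-PD-1-Fc against Ctrl, 3157 genes and 3 lists for VHH-OD-PD-1-Fc against VHH-OD-Fc, 3978 in the F test and r = 0.845 for VHH-PD-1-Fc with VHH-OD-PD-1-Fc. Rescaling to TPM gave 73 for VHH-OD-PD-1-Fc against VHH-PD-1-Fc. Quantile normalization gave 16 and 7 lists for VHH-PD-1-Fc and VHH-OD-PD-1-Fc against Ctrl. Fitting only the groups contrasted, with fewer samples, gave 3821 for VHH-PD-1-Fc against Ctrl and 46 for VHH-OD-PD-1-Fc against VHH-PD-1-Fc. Library quality weights gave 4 for VHH-OD-Fc against Ctrl, 9901 genes and 8 lists for VHH-OD-PD-1-Fc against Ctrl, 11 against VHH-PD-1-Fc, 8716 against VHH-OD-Fc and 38 for the difference from additivity. A fold of at least 2, which can only lower counts, gave 1249 and 1122 for VHH-PD-1-Fc and VHH-OD-PD-1-Fc against Ctrl, 36 against VHH-PD-1-Fc, 1030 against VHH-OD-Fc and 1569 in the F test. An estimated correlation gave 0 lists in each of the 6 comparisons. Fry gave 0, 25 and 17 lists for VHH-OD-Fc, VHH-PD-1-Fc and VHH-OD-PD-1-Fc against Ctrl, 1 against VHH-PD-1-Fc and 3 for the difference from additivity.

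Libraries of the same number showed no clear pairing. After removal of group means, 1 of 18 pairs of the same number had r above 0.1 (range -0.154 to 0.184), and pairs of different numbers reached 0.434. Pairs that include a VHH-OD-PD-1-Fc library (r at most 0.0569) could hardly show pairing, since those libraries differ little from their mean. The number as a block gave 28 for VHH-OD-PD-1-Fc against VHH-PD-1-Fc and 3 for the difference from additivity. Counting the VHH-OD-PD-1-Fc libraries as 1 sample, which leaves fewer samples, gave 1329 against Ctrl, 3 against VHH-PD-1-Fc, 1098 against VHH-OD-Fc, 3 for the difference from additivity and 4227 in the F test. Removal of length and GC trends gave r = 0.842 for VHH-PD-1-Fc with VHH-OD-PD-1-Fc. Leaving out the 3 libraries apart gave 524 for VHH-OD-PD-1-Fc against VHH-PD-1-Fc, 56 for the difference from additivity and 8 lists for VHH-OD-PD-1-Fc against Ctrl. The correlations were then 0.179 for VHH-OD-Fc with VHH-PD-1-Fc, 0.153 with VHH-OD-PD-1-Fc and 0.834 for the latter with VHH-PD-1-Fc, and that of the OD arm without and with the PD-1 arm turned to -0.0370.

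Medians of gene lists that were called before or after and changed sign were as follows. DNA replication in VHH-OD-PD-1-Fc against VHH-OD-Fc turned to -0.0291 after rescaling to TPM, when the median of all genes also moved, from -0.11 to -0.34. For VHH-OD-Fc against Ctrl, leaving out the 3 libraries apart turned neutrophils to -0.17, endothelium to -0.13, skeletal muscle to -0.0648, tumour epithelium to -0.0280, oxidative phosphorylation to -0.0502 and haemoglobin genes to -0.21. It turned macrophages to 0.12 for VHH-OD-PD-1-Fc against VHH-PD-1-Fc and haemoglobin genes to 0.79 for the difference from additivity. With 1 library left out, VHH-OD-Fc against Ctrl gave -0.32 (without VHH-OD-Fc replicate 2) to 0.31 (without VHH-OD-Fc replicate 1) for neutrophils and -0.10 (without Ctrl replicate 1) to 0.30 (without Ctrl replicate 2) for tumour epithelium. VHH-OD-PD-1-Fc against VHH-PD-1-Fc gave -0.54 (without VHH-PD-1-Fc replicate 1) to 0.12 (without VHH-PD-1-Fc replicate 2) for macrophages and -0.23 (without VHH-PD-1-Fc replicate 3) to 0.0629 (without VHH-PD-1-Fc replicate 1) for tumour epithelium. The difference from additivity gave -1.10 (without VHH-OD-Fc replicate 1) to 1.65 (without VHH-OD-Fc replicate 2) for skeletal muscle.

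Leaving out 1 library gave 0 to 1 genes and 13 to 28 lists for VHH-OD-Fc against Ctrl, 5353 to 6858 and 5 to 12 for VHH-PD-1-Fc, and 4522 to 6907 and 4 to 8 for VHH-OD-PD-1-Fc. It gave 9 to 538 genes and 11 to 19 lists for VHH-OD-PD-1-Fc against VHH-PD-1-Fc, 4179 to 6565 and 6 to 9 against VHH-OD-Fc, 3 to 105 and 14 to 21 for the difference from additivity and 5924 to 7705 genes in the F test. The correlations ranged from 0.149 to 0.389 for VHH-OD-Fc with VHH-PD-1-Fc, 0.227 to 0.437 for VHH-OD-Fc with VHH-OD-PD-1-Fc, 0.835 to 0.879 for VHH-PD-1-Fc with VHH-OD-PD-1-Fc and -0.0446 to 0.178 for the OD arm without and with the PD-1 arm, where the negative value came without VHH-OD-Fc replicate 2. Count-based alternatives were not run, since the table holds FPKM. Depth was estimated, not given, and limits low genes most.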

Other observations

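All values here were chosen for printing after they were seen. In VHH-PD-1-Fc against Ctrl 6 of 7 genes of lymph node stroma and homing fell, and 6 adjusted over the list alone, with Ccl21a, a chemokine of lymph node stroma, at -3.03 (SE 0.71, n = 3 per group). Of 13 checkpoint ligand genes 6 fell, and 6 adjusted over the list alone. The mean log2 value of the former list was 3.38, 2.38 and 3.15 in Ctrl replicates 1 to 3 and 2.21, 3.26 and 2.18 in the VHH-OD-Fc libraries. In the same order the B cell list was at 2.85, 0.99 and 3.13 and at 1.56, 2.84 and 0.97, and the plasma cell list at 5.74, 2.62 and 4.17 and at 3.28, 5.23 and 2.72. In VHH-PD-1-Fc these 3 lists were at 1.20 to 1.52, 0.80 to 1.12 and 2.15 to 3.09. Neither the list of lymph node stroma nor that of checkpoint ligands was called by camera. Fxyd5, a membrane protein of the FXYD family, rose by 0.30 (SE 0.07, adjusted p = 0.0069). Scaling bears on a rise of this size, since the median of all genes was -0.19 as deposited and -0.43 after rescaling to TPM. In VHH-OD-PD-1-Fc against Ctrl, described next, these medians were -0.14 and -0.37. The list of Na,K-ATPase and FXYD proteins (median -0.05) was not called in VHH-PD-1-Fc against Ctrl. Atp1b1 was lower, at 5.91 FPKM in Ctrl (SD 5.32) and 1.80 in VHH-PD-1-Fc (SD 1.55).

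In VHH-OD-PD-1-Fc against Ctrl Fxyd5 rose by 0.46 (SE 0.07, adjusted p = 0.00085), and its adjusted p was 0.055 with the 3 libraries counted as 1 sample. Zfp146, a zinc finger protein, fell by 2.34 (SE 0.12, adjusted p = 3.7e-06) and kept its call in that setting (adjusted p = 0.0028). Foxp3, the transcription factor of regulatory T cells, was below the filter, at 0.294 FPKM in Ctrl and 0.106, 0.0447 and 0.0841 in VHH-OD-Fc, VHH-PD-1-Fc and VHH-OD-PD-1-Fc.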
